A study of Rattus norvegicus with 3 samples.

How the data were processed

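Total RNA from whole common carotid arteries was labelled with Cy3 and hybridised to one-colour Agilent rat arrays, per the labels. The data analysed here were 3 scanner files, 1 each for an uninjured artery, an artery 7 days and an artery 21 days after balloon injury, and 1 table of values for the same arrays. Groups came from the sample titles. Other arrays of the experiments that the design text mentions were not analysed here.

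Spot intensity values were written by Agilent Feature Extraction, version 10.7.3.1 for the uninjured and day 21 arrays and version 11.0.1.1 for the day 7 array, per the file headers. The submitters' processing notes name version 10.7.3.1. The processed signal is background-subtracted and detrended within each array and not normalized between arrays, per the file headers. The headers also give the array design, which is the same for the uninjured and day 21 arrays and a different one for day 7, and show that the uninjured and day 21 arrays came from 1 scan. The authors' deposited table holds log2 values of 9260 rows, with medians of 7.64, 7.62 and 7.64 for uninjured, day 7 and day 21 and nearly equal quartiles. How it was normalized is not given in the sources used here. Set against the scanner signals, it is on a log2 scale and runs in the same direction, while the centring of its columns stays unknown. Its row names are all probes of the day 7 design, and 3957 of them are not on the design of the other arrays.

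Control spots and spots with an outlier flag were left out (0.242%, 1.46% and 0.274% of gene spots on the uninjured, day 7 and day 21 arrays), spots of 1 probe were averaged on the log2 scale, and each array's 75th percentile of log2 signal was subtracted. The raw 75th percentiles were 51.6, 367 and 143 intensity units. The plan, fixed before the data were examined, did not foresee different designs. Read literally it takes that percentile over all probes of each array. Because the designs hold different probes, comparisons with day 7 were instead restricted to the 10602 probes on both designs (10583 unflagged on all 3 arrays) and scaled on these, a choice made after the designs were seen and before any ratio was computed. The literal version is given as an alternative and changes the counts strongly. Day 21 was compared with uninjured on all 40989 unflagged probes of their common design.

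The scanner files held no gene names. Sequence accessions were matched without versions to a RefSeq table of the GRCr8 assembly, used only for names: 17505 probes (42.7%) of the older design matched, giving 13833 genes, and 8040 (76.0%) of the shared probes, giving 7796 genes. The array designs are on rn4, and no coordinates are given. A gene was represented by its probe with the highest mean signal over the arrays compared on that design. Of 1784 genes with several measured probes in the comparison of day 21 with uninjured, 554 had probes of opposite sign, 14 of them by 2-fold or more in each direction. The corresponding numbers were 48 and 6 of 105 genes for day 7 with uninjured, and 53 and 5 of 121 for day 21 with day 7.

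With 1 array per group no model was fitted. Genes well above background on both arrays were described by a threshold of 2-fold. A gene well above background on 1 array only has a bound: the bright signal over the higher of the dim array's lowest signal well above background and the gene's own signal there, written as "at least". Bounds of 2-fold or more were found for 501 genes higher and 273 lower at day 7, 221 higher and 304 lower at day 21, and 113 higher and 673 lower at day 21 against day 7. The technical spread is the SD of replicate spots, interpolated over signal (median SD 0.133, 0.103 and 0.134 on the uninjured, day 7 and day 21 arrays).

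In all 36 gene lists, written before the data were examined, cover pathways, cell types and sample quality. A list of at least 3 measured genes was described by its median log2 ratio, bounds included, and by the percentile of that median among 10000 random lists of equal size matched in 20 bins of signal, as a description of these arrays. Lists beyond the central 95% were called higher or lower: 11 higher and 5 lower of 35 at day 7, 12 and 6 of 36 at day 21, and 5 and 5 of 35 between the days, where 0.9 per side would be expected by chance for independent genes. Genes of a list vary together, so such percentiles are extreme more often than by chance.

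Genes named in the text are the 10 highest and 10 lowest ratios per comparison among genes with a symbol that is not a placeholder and without a probe of opposite sign, the 5 largest bounds in each direction, and up to 4 members of each list in the direction described with any member that shows the opposite. The plan took symbols from the files, which held none, so the RefSeq symbols were used. Some genes that the rule selects are not reported here. The tests of brightness, scaling and background on the Schwann cell and endothelial lists were replaced 2 times after their results were seen: percentiles among random lists, which were at their limit, gave way to intervals of the median over members, and these to the amount that a correction took from the members, set against 50% of the list median.

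Alternatives were median scaling, quantile normalization, cyclic loess, the mean of all probes of a gene, the authors' deposited table, a filter for signals above background on all 3 arrays, no filter, a 3-fold threshold, random lists without matching, and members on both arrays only. Added after seeing the data were normexp (offset 50) on median signals, since the mean-signal column that was planned is not in the scanner files used here, scaling on each array's own design, rows of the authors' table with a shared probe, day 21 on shared probes only, and all probes with or without a symbol. The scripts were tested on simulated data with 200 changed genes. For day 21 with uninjured (9420 genes), 50 of 50 genes changed 3-fold were called, with 11 false calls, and for day 7 with uninjured (5248 genes) 49 of 50, with 104 false calls from spot noise alone. For day 21 with day 7 (5640 genes) it was 48 of 50, with 151 false calls. Of 2000 unchanged lists per comparison, 3.8% (day 7), 3.7% (day 21) and 4.05% (between the days) lay outside the central 95%; this number of lists was raised from 200 after a first run gave a higher share for day 21. Scaling and normalization used R 4.3.3 with limma 3.58.1, and the rest Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.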

Results

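Gene expression was measured in the whole common carotid artery of male Wistar rats, either uninjured or taken 7 or 21 days after balloon injury, in which an inflated balloon strips the endothelium and stretches the smooth muscle wall. The files held 3 one-colour arrays, 1 per group. There were therefore no replicates: no test was possible, no p-value is given, and every difference is a difference between 2 arrays. The design text speaks of independent experiments at each time with different rats; further arrays were not analysed here. The uninjured and day 21 arrays were of one design and one scan, while the day 7 array was of another design, with its own scan and a later release of the scanner software. The share of probes well above background was 59.8% on the uninjured array, 76.5% on the day 7 array and 66.7% on the day 21 array, and no spot was saturated. Values below are log2 ratios of the scaled signals, and the figure after ± is the SD that replicate spots on the arrays give for that ratio. This spread is technical only. Different probes of one gene differed by more, with an SD of 0.56 in the comparison of day 21 with uninjured and of 0.99 in that of day 7 with uninjured.

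The comparison of day 7 with uninjured addressed the early response to the injury. Genes of cell division and of inflammatory cells were higher in the injured artery, and contractile smooth muscle genes were lower. Cdk1, the kinase that drives entry into mitosis, was 70.0-fold higher (log2 ratio 6.13 ± 0.21). The MHC class II gene RT1-Bb was 67.0-fold higher (6.07 ± 0.32), and Tpm2, a tropomyosin of the contractile apparatus, was 14.0-fold lower (-3.80 ± 0.13). Of 5248 genes well above background on both arrays, 845 were at least 2-fold higher at day 7 and 854 at least 2-fold lower. The median over these genes was -0.01.

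Contractile smooth muscle genes had a median log2 ratio of -2.36 at day 7, below all 10000 random lists matched on signal, and 10 of the 12 measured were at least 2-fold lower. Cnn1 (calponin) was at -3.08 ± 0.11, Csrp1 at -2.94 ± 0.13 and Tpm1 at -2.85 ± 0.13, whereas the integrin Itga7 was at 0.83 ± 0.14. Channels and receptors of vascular tone had a median of -1.27, with 11 of 18 genes at least 2-fold lower (a place outside the random range kept in 9 of 11 alternatives), among them prostacyclin synthase (Ptgis, -3.07 ± 0.11) and the adrenergic receptor Adra1d (-2.34 ± 0.09). In the same list the angiotensin receptor gene Agtr1a was higher, at 2.56 ± 0.06. Subunits of oxidative phosphorylation had a median of -1.40 and 18 of 26 were at least 2-fold lower, as were Atp5f1b (-2.50 ± 0.11) and Ndufa5 (-2.49 ± 0.13).

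Mitosis genes had a median of 2.35 at day 7, above all 10000 random lists, and 10 of 13 were at least 2-fold higher. Ccnb1 (cyclin B1) was at 4.94 ± 0.31, Kif20a at 4.76 ± 0.19 and Ube2c at 4.37 ± 0.20. DNA replication genes had a median of 1.29 (0.11 with each array scaled on its own design, still above the random lists), with 10 of 16 at least 2-fold higher, such as the chromatin assembly gene Chaf1b (2.87 ± 0.18). Pcna was at 0.47 ± 0.14.

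Macrophage and monocyte genes were at a median of 3.01 at day 7, with 19 of 21 at least 2-fold higher. Gpnmb was at 4.46 ± 0.18, Tyrobp at 4.23 ± 0.14 and Laptm5 at 4.03 ± 0.16. Neutrophil genes had a median of 1.83 (outside the random range in 10 of 11 alternatives), with 6 of 7 at least 2-fold higher, including the calprotectin genes S100a8 (2.40 ± 0.25) and S100a9 (2.35 ± 0.18). The MHC class II list was at 3.18 and the complement list at 1.81 (above the random range in 10 of 11 alternatives), with Cd74 at 5.14 ± 0.19 and C3 at 4.26 ± 0.20. T and NK cell genes had a median of 0.20, inside the range of random lists.

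Matrix genes were mixed at day 7. The list of non-collagen matrix glycoproteins and proteoglycans had a median of 0.87, with 10 of 21 at least 2-fold higher: tenascin C (Tnc) was at least 24.9-fold higher, being not well above background in the uninjured artery, and Comp was at 3.09 ± 0.17 and osteopontin (Spp1) at 2.83 ± 0.04. That median was -0.18 when each array was scaled on its own design, although the list stayed above the random lists drawn under that scaling. In the same list Ccn2 was at -2.43 ± 0.04. Matrix proteases and their inhibitors had a median of 1.22 (above the random range in 10 of 11 alternatives), with the macrophage elastase Mmp12 at least 138-fold higher and Mmp7 at least 47.2-fold higher. Collagens and collagen-processing enzymes did not stand apart from random lists (median -0.08), with Col8a1 at 2.24 ± 0.18, Col1a1 at 1.26 ± 0.13 and Col3a1 at -1.06 ± 0.13.

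Markers of other cell types also differed at day 7. Endothelial genes had a median of 1.69 (0.47 with each array scaled on its own design), with 10 of 14 at least 2-fold higher, such as Cldn5 (2.88 ± 0.18) and Emcn (2.59 ± 0.32). Schwann cell and nerve genes had a median of 2.71 (0.77 with normexp), with 9 of 12 at least 2-fold higher, such as the neurotrophin receptor gene Ngfr (4.75 ± 0.10) and Sox10 (4.10 ± 0.18). Fibroblast genes were at -0.26 and skeletal muscle genes at -0.02, both inside the range of random lists. Adipocyte genes had a median of -1.08, with 6 of 11 at least 2-fold lower and 4 at least 2-fold higher. The basement membrane list (median -1.10, 5 genes) and the growth factor list (median 0.74, 15 genes) lay just outside the random range. Under 11 alternatives these places were kept in 3 and 6, and that of the adipocyte list in 6. The signs of all 3 lists turned in the authors' deposited table. On its rows with a shared probe only the sign of the adipocyte list turned.

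Under the alternatives the smallest medians at day 7 were 0.77 for mitosis, 0.36 for complement, 0.00 for matrix proteases, 0.35 for neutrophil, 1.79 for macrophage and 1.96 for MHC class II genes, and those nearest to 0 were -2.10 for contractile, -1.11 for oxidative phosphorylation and -0.92 for vascular tone genes.

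Among genes well above background on both arrays, the largest differences at day 7 were those of Apod, which encodes the lipid carrier apolipoprotein D (9.29 ± 0.23, 627-fold), and the imprinted non-coding RNA H19 (6.82 ± 0.18, 113-fold). C1qtnf3 (5.84 ± 0.32), C2 of the complement system (5.75 ± 0.27), Fxyd6 (5.55 ± 0.20) and Slamf9 (5.02 ± 0.17) followed. The lowest ratio was that of Abra, which encodes an actin-binding protein of muscle (-5.73 ± 0.22). Csrnp1 (-4.56 ± 0.76), B3gat2 (-4.49 ± 0.23), Id4 (-4.16 ± 0.15), Spink8 (-3.86 ± 0.08), Rasd2 (-3.76 ± 0.13) and Itih3 (-3.75 ± 0.67) were also among the 10 lowest, together with the immediate-early transcription factor genes Nr4a3 (-4.40 ± 0.13) and Atf3 (-4.35 ± 0.12). As a whole the immediate-early and heat-shock list, which marks handling of tissue, was at -0.53 and inside the random range. Even so, 5 of its 12 genes, Nr4a3 and Atf3 among them, were at least 2-fold lower, and 1 was at least 2-fold higher. At day 21 the list was at -0.15 and inside the random range, but above it in 3 of 10 alternatives, such as 0.22 on shared probes. The bounds for genes seen on the day 7 array alone included Fcgr2b (at least 61.7-fold higher), Glul (at least 45.1-fold) and Myoc (at least 43.7-fold). In the other direction Alb was at least 21.0-fold lower and Myh6 at least 15.9-fold lower.

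The day 7 array differed from the others in design, scan and software as well as in time after injury, so group and batch cannot be told apart in any comparison with it. Of the genes at least 2-fold apart, 49.7% were higher at day 7, against 26.2% with median scaling and 5.45% when each array was scaled on all probes of its own design (180 higher, 3120 lower), so the balance of higher and lower genes depends on the scaling.

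**Figure D1:**
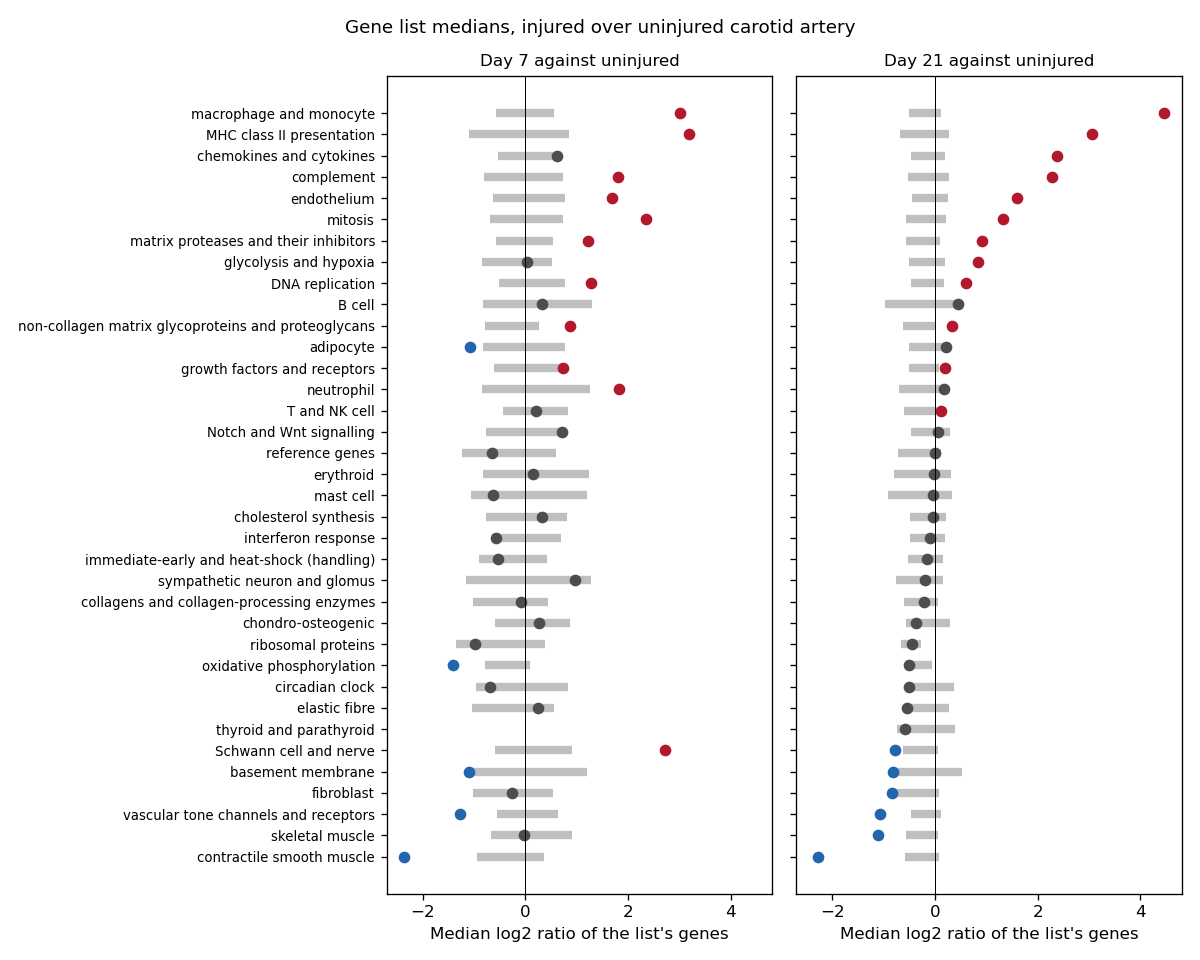
Median log2 ratio of each gene list (points, x axis) for day 7 (left) and day 21 (right) over uninjured, with grey bars for the central 95% of 10000 random lists matched on signal. Red points lie above that range, blue points below it and dark grey points inside it: at day 21 the macrophage and monocyte list is highest, at 4.47, and the contractile smooth muscle list lowest, at -2.28.

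The comparison of day 21 with uninjured addressed the later artery, and both arrays came from one design and one scan. Macrophage genes were the highest, and contractile smooth muscle genes remained low. Lysozyme (Lyz2) was 242-fold higher (7.92 ± 0.16) and the haem-degrading enzyme gene Hmox1 161-fold higher (7.33 ± 0.06), while the smooth muscle actin gene Actg2 was 21.0-fold lower (-4.39 ± 0.13). Of 9420 genes well above background on both arrays, 858 were at least 2-fold higher and 1293 at least 2-fold lower. The median over these genes was -0.20.

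Macrophage and monocyte genes had a median log2 ratio of 4.47 at day 21, above all 10000 random lists, and 25 of 26 were at least 2-fold higher. Gpnmb was 108-fold higher (6.75 ± 0.17), and the lipid-sensing receptor gene Trem2 was 82.9-fold higher (6.37 ± 0.17). The integrin gene Itgb2 was at least 149-fold higher and Fcgr2b at least 108-fold higher, both not well above background in the uninjured artery. Spi1 was at -0.18 ± 0.31. Chemokines and cytokines had a median of 2.37, with 12 of 23 at least 2-fold higher, including Il18 (5.26 ± 0.32), Il1rn (4.60 ± 0.19) and Ccl7 (4.43 ± 0.19), whereas Ccl21 was at -3.17 ± 0.31. The complement list was at 2.29, with C3 at 5.57 ± 0.20 and C5ar1 at 5.04 ± 0.18, and the MHC class II list at 3.06, with Cd74 at 5.78 ± 0.18. T and NK cell genes had a median of 0.13, above the random range, with 7 of 20 at least 2-fold higher, such as Cd8b (3.28 ± 0.20) and Cd6 (2.59 ± 0.20). With normexp background correction that median was 0.00, and the list stayed above the random range in 7 of 10 alternatives.

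Contractile smooth muscle genes had a median of -2.28 at day 21, below all 10000 random lists, and 20 of 21 were at least 2-fold lower. Desmin (Des) was at -3.23 ± 0.14, Cnn1 at -3.13 ± 0.14 and Casq2 at -3.10 ± 0.14. Vascular tone genes had a median of -1.08, with 14 of 26 at least 2-fold lower, such as the calcium channel subunit gene Cacnb2 (-2.55 ± 0.16) and the calcium release channel gene Itpr1 (-1.87 ± 0.14). Skeletal muscle genes were at -1.12, with 12 of 23 at least 2-fold lower, led by creatine kinase (Ckm, -4.01 ± 0.16). Fibroblast genes had a median of -0.83, with Gpc3 at -2.33 ± 0.16 and Cygb at -2.00 ± 0.13, although Lum was at 2.19 ± 0.13, and the list lay inside the random range in 2 of 10 alternatives, those on shared probes. Schwann cell and nerve genes were at -0.77, with 5 of 19 at least 2-fold lower, such as Gldn (-2.19 ± 0.18). On the probes of both designs their median was -0.92 over 9 genes and inside the random range. Basement membrane genes were at -0.81, with Lamb2 at -1.98 ± 0.14, and were below the random range in 6 of 10 alternatives.

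Cell division genes were still higher at day 21: the mitosis list had a median of 1.32 and 10 of 17 genes at least 2-fold higher, with Cdk1 at 4.41 ± 0.23 and Plk1 at 2.60 ± 0.26. The DNA replication list was at 0.61, with Fen1 at 1.96 ± 0.19. Matrix proteases and their inhibitors had a median of 0.91, with Mmp12 at least 370-fold higher and cathepsin S (Ctss) at 5.42 ± 0.16. Non-collagen matrix glycoproteins had a median of 0.33, with Comp at 3.43 ± 0.17 and Spp1 at 2.94 ± 0.04. Collagens again did not stand apart (median -0.21). Oxidative phosphorylation genes, at -0.50, were inside the random range, but below it in 6 of 10 alternatives. Glycolysis and hypoxia genes had a median of 0.84, with 9 of 21 at least 2-fold higher (above the random range in 8 of 10 alternatives), such as Ankrd37 (2.29 ± 0.20) and lactate dehydrogenase (Ldha, 1.32 ± 0.05). The growth factor list was at 0.20, above the random range in 7 of 10 alternatives, with Igfbp3 at 3.75 ± 0.19. Endothelial genes had a median of 1.60, with 13 of 21 at least 2-fold higher: Emcn was at 3.37 ± 0.32 and the VEGF receptor gene Kdr at 2.46 ± 0.17, while Cdh5 was at -0.21 ± 0.23 and Mmrn1 at -1.78 ± 0.27.

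The smallest medians at day 21 under the alternatives were 0.43 for mitosis, 0.21 for DNA replication, 0.10 for matrix glycoprotein, 0.29 for matrix protease, 0.24 for glycolysis, 1.03 for chemokine, 1.13 for endothelial, 2.09 for complement, 2.60 for MHC class II and 4.33 for macrophage genes, and those nearest to 0 were -1.65 for contractile, -0.60 for vascular tone and -0.64 for skeletal muscle genes.

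The 10 highest genes at day 21, of those well above background on both arrays, also held Tbxas1, which encodes thromboxane synthase (6.20 ± 0.20), Slamf9 (6.02 ± 0.20), RT1-Bb (5.86 ± 0.32), the leukocyte actin regulator Coro1a (5.81 ± 0.20) and C2 (5.80 ± 0.27). Among the lowest were Abra (-5.64 ± 0.18), the actin-bundling gene Pls3 (-5.58 ± 0.14), the myosin phosphatase catalytic subunit gene Ppp1cb (-5.51 ± 0.15), Spink8 (-5.32 ± 0.15), Asb12 (-4.19 ± 0.27), Sostdc1 (-3.98 ± 0.32), Vwc2 (-3.94 ± 0.23) and the purinergic receptor gene P2rx1 (-3.89 ± 0.15). Pls3 was read at its brighter probe of 2. Of genes seen on the day 21 array alone, Akr1b8 was at least 153-fold higher, and of those seen on the uninjured array alone, Myh6 was at least 24.1-fold lower and Slc22a3 at least 18.9-fold lower.

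Of the genes at least 2-fold apart at day 21, 39.9% were higher. This share was 77.1% with median scaling, 55.6% with quantile normalization and 64.9% with cyclic loess, and the median of all genes was then 0.28, -0.06 and 0.05.

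The comparison of day 21 with day 7 addressed the change over time within the injured artery, and crosses the 2 array designs. Macrophage genes were higher at day 21, and genes of mitosis, of neutrophils and of Schwann cells were lower. Hmox1 was 19.8-fold higher at day 21 than at day 7 (4.31 ± 0.04), and Apod was 1206-fold lower (-10.24 ± 0.23). Of 5640 genes well above background on both arrays, 606 were at least 2-fold higher and 1126 at least 2-fold lower. The median over these genes was -0.19.

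Macrophage and monocyte genes were at a median of 1.56 between the days, with 14 of 21 at least 2-fold higher at day 21, including Itgb2 (3.05 ± 0.11) and Ctss (2.94 ± 0.14). The chemokine and cytokine list was at 0.62, with Ccl3 at 3.02 ± 0.20, Ccl2 at 2.73 ± 0.04 and Csf1 at -2.71 ± 0.13, and the complement list at 0.79, with C6 at 3.27 ± 0.12. Oxidative phosphorylation genes had a median of 0.56, with Atp5f1b at 2.03 ± 0.13. The B cell list was at 1.43 over 7 genes, with Pou2af1 at 2.66 ± 0.22 and Blk at -1.45 ± 0.53, and above the random range in 7 of 8 alternatives.

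Mitosis genes had a median of -1.81 between day 7 and day 21, below all 10000 random lists, with 10 of 13 at least 2-fold lower, such as Kif20a (-3.08 ± 0.16) and Aurkb (-2.43 ± 0.23). DNA replication genes were at -0.84, inside the random range but outside it in 6 of 11 alternatives. Neutrophil genes were at -2.14, below the random range in 10 of 11 alternatives, with S100a9 at -2.14 ± 0.15. Schwann cell and nerve genes were at -3.81, also below all random lists, and 11 of 12 were at least 2-fold lower, with Ngfr at -5.86 ± 0.11 and Sox10 at -5.02 ± 0.17. The myelin genes Prx and Mal were at least 51.2-fold and at least 24.6-fold lower. Skeletal muscle genes were at -1.38, with Actn3 at -3.43 ± 0.20, and the list of sympathetic neurons at -2.21 over 5 genes, with Npy at -3.83 ± 0.05. These places below the random range were kept in 8 of 11 alternatives for skeletal muscle and in 5 of 8 for sympathetic neurons. Contractile smooth muscle genes (median -0.24) and endothelial genes (median 0.15) did not stand apart from random lists between the days.

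Between the days the medians nearest to 0 under the alternatives were 1.42 for macrophage, 0.54 for chemokine, 0.79 for complement and 0.01 for B cell genes, and -0.44 for mitosis, -0.77 for neutrophil, -2.10 for Schwann cell, -0.75 for sympathetic and -0.01 for skeletal muscle genes.

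Further genes far apart between the days were B4galt6 (4.20 ± 0.27), Hsd11b1 (3.65 ± 0.19), Akr1c15 (3.49 ± 0.25) and the lipoprotein lipase gene Lpl (3.22 ± 0.12), all higher at day 21. Fxyd6 (-7.05 ± 0.23), Sostdc1 (-6.58 ± 0.30), C1qtnf3 (-5.76 ± 0.23), Pllp (-5.57 ± 0.35), Clec1b (-5.39 ± 0.26), H19 (-5.21 ± 0.16) and the gap junction gene Gjb2 (-4.96 ± 0.35) were lower. The potassium channel gene Kcna1 was at least 54.0-fold lower.

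Of the genes at least 2-fold apart between the days, 35.0% were higher at day 21, and this share was 65.9% with median scaling, 58.9% with quantile normalization, 56.5% with cyclic loess and 95.2% when each array was scaled on its own design.

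**Figure D2:**
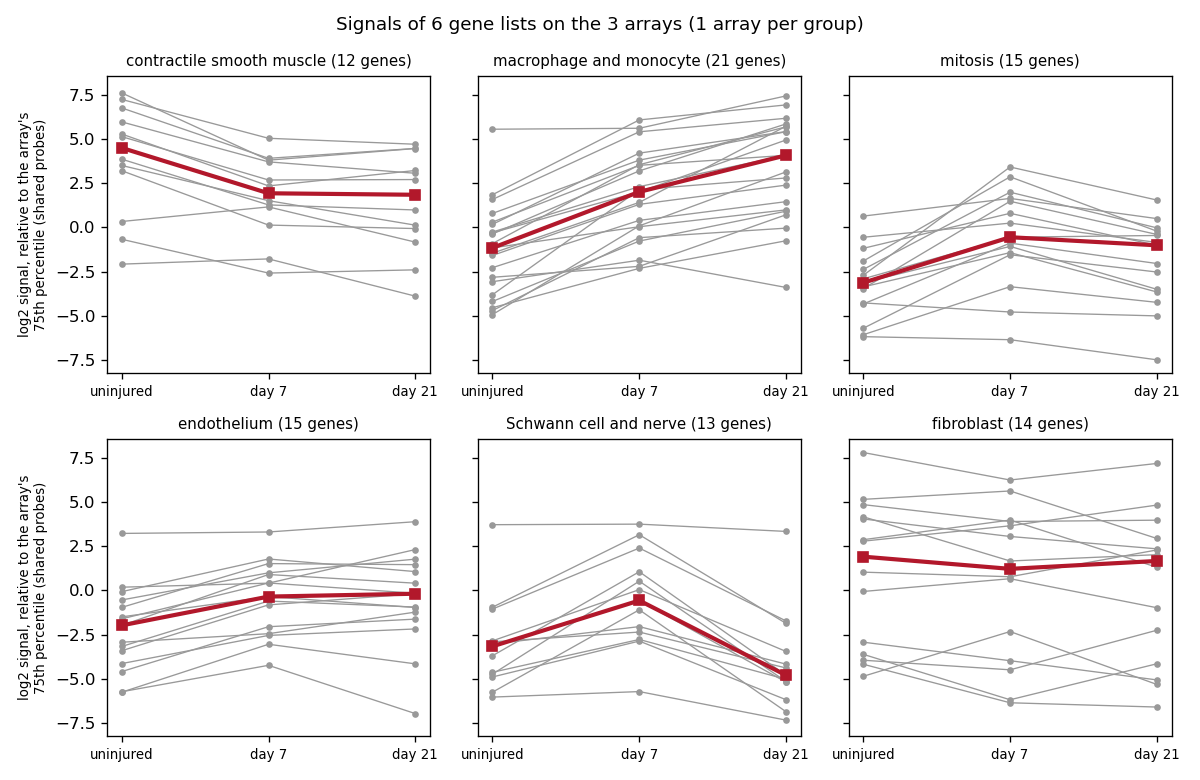
Scaled log2 signal (y axis, relative to the array's 75th percentile over the probes on both designs) of the genes of 6 lists on the uninjured, day 7 and day 21 arrays, 1 array each. Grey lines are single genes, including genes not well above background, and red squares their median, which for Schwann cell and nerve genes is -3.16, -0.57 and -4.80 in that order. The lowest signals well above background were -3.92, -4.47 and -5.22 in the same order, so differences between dim genes are not measured changes.

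The ratios of both days over uninjured were set against each other over 5170 genes well above background on all 3 arrays. Across genes, which are not independent replicates, Pearson's correlation was 0.58 and Spearman's rank correlation 0.46. Both ratios share the single uninjured array, and unchanged arrays simulated with the noise of replicate spots gave a Pearson correlation of 0.35 from that alone. The covariance was 0.73, against 0.02 in the simulation. The share of genes with the same sign at both days was 65.0%, and 65.9% in the simulation. The simulated arrays hold no change in any gene, so noise alone sets their signs and their correlation. Their share of signs and correlation therefore do not give the part of 65.0% or 0.58 that comes from the shared array. At least 2-fold higher at both days were 311 genes, where independent lists would share 76.4, and 326 were at least 2-fold lower at both, against 133. These numbers for independent lists leave out the shared array, and the simulation, which holds spot noise only, gave 0.38 and 0.48 such genes. A single control array cannot be split, so part of the excess may come from it.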

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

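The tests in this part on the Schwann cell list were chosen only after the result was seen. Differences between the days below were not tested, since each group is 1 array.

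Schwann cell and nerve genes went opposite ways, with a median log2 ratio of 2.71 at day 7 (12 genes on shared probes) and -0.77 at day 21 (19 genes on the full design), although on shared probes the day 21 median was -0.92 over 9 genes and inside the random range, as it was in 2 of 10 alternatives. Independent scatter of single probes from crossing the designs is argued against, since random lists carry it too and none of 10000 reached the median of 2.71 (upper end of their central 95% 0.90). A shift that varies with brightness is argued against as the larger part. Quantile and loess scaling took at most 6.95% of the median from the members (95% intervals under either reaching up to 13.2%) and left medians of 2.68 and 2.48. The interval of the median over members under quantile scaling, from 0.656, just reached the random range, up to 0.663. That test did not cover an offset common to all genes. Scaling each array on its own design moved the median of all genes at day 7 from -0.01 to -1.23. Background at low signal stays open, since the normexp setting cannot decide it. That setting adds an offset of 50 to every signal, while the raw 75th percentiles were 51.6 (uninjured) and 367 (day 7). The offset shrinks the ratios of dim genes whatever their background. Normexp took 40.7% (30.4% to 71.6%) and left a median of 0.77. Nerve tissue taken with the artery and an untested response to injury stay open and cannot be separated from the array's own batch. The 6 measured myelin genes had a median of 2.75 (0.51 to 3.95). They are members of this same list of 12 genes, so their median cannot decide for or against nerve tissue.

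Over the 5170 genes measured on all 3 arrays, 67 were at least 2-fold higher at day 7 and at least 2-fold lower at day 21 than in the uninjured artery, and 11 went the reverse way. These are few beside the 311 higher and 326 lower at both days. At day 7, 809 genes were higher and 852 lower, and at day 21, 488 higher and 805 lower. The balance of 67 and 11 was not recomputed under other scalings, which move all day 7 ratios. On shared probes the named genes among them were Fxyd6 (5.55 at day 7 and -1.50 at day 21), Ngfr (4.75 and -1.11), Clec1b (2.95 and -2.45) and Sostdc1 (2.44 and -4.13) in the first direction. In the second were B4galt6 (-1.82 and 2.38), Akr1c15 (-1.83 and 1.66) and Gcgr (-1.76 and 1.42).

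Outside the gene probes, 180 of 320 spike-in control spots were well above background on the day 7 array, against 111 on the uninjured and 103 on the day 21 array. Negative control spots were well above background at 6 of 153 positions on the day 7 array and at 0 on the others.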

How the results depend on the processing

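No paired analysis was possible because the groups share only replicate number 1 and no model was fitted. The normexp correction on mean signals that was planned was not run, as the column is not in the files used here. Normexp on median signals, own-design scaling, shared-probe settings and all-probe settings were chosen after seeing the data. Of the lists outside the random range, 9 of 16 kept their call under all alternatives run for day 7, 12 of 18 for day 21 and 6 of 10 between the days. The number of lists outside ranged from 13 to 18 at day 7, from 17 to 24 at day 21 and from 9 to 12 between the days. The causes below were not tested, except where fewer or more genes enter by construction. Leaving out the background filter gave 3372 genes at least 2-fold apart at day 7 (1828 higher, 1544 lower; 1699 with it), 4515 at day 21 (1347, 3168; 2151 with it) and 3088 between the days (1003, 2085; 1732 with it).

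Counts are given as higher and lower. Median scaling gave 508 and 1429 at day 7, 1644 and 489 at day 21, and 1214 and 629 between the days. Quantile normalization gave 787 lower at day 21, 948 and 661 between the days, and cyclic loess 611 lower at day 21 and 671 lower between the days. Own-design scaling gave 180 and 3120 (3300) at day 7 and 3248 and 162 (3410) between the days, and moved the median of all genes to -1.23 and 1.18. Normexp gave 339 and 514 (853) at day 7 and 1054 at day 21, 265 of them lower. The authors' table gave 1950 and 2525 (4475) at day 7, 744 lower at day 21, and 2508 and 1708 (4216) between the days, and its rows with a shared probe 470 and 1736 at day 7 and 1728 and 265 between the days. No background filter was applied to that table. Its counts cover 7485 genes, or 4288 with a shared probe, against 5248 filtered genes in the main comparison at day 7. A 3-fold threshold gave 380 and 380 (760), 464 and 390 (854), and 252 and 542 (794). At day 21, probes on both designs gave 497 higher, the filter on all 3 arrays 488 and 805 (1293), and all probes with or without a symbol 1644 and 4417 (6061).

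The correlation of the days was 0.59 with quantile normalization, 0.61 with loess, 0.54 with normexp and 0.40 in the authors' table. Over single rows of that table it was 0.53 for the 5303 with a shared probe and 0.34 for the 3957 without one. Signs turned for basement membrane (0.17), growth factors (-0.079) and adipocyte (0.54, and 0.10 with a shared probe) at day 7 in the authors' table, and for matrix glycoproteins (-0.18) and growth factors (-0.48) at day 7 with own-design scaling. The median of T and NK cells at day 21 reached 0.00 with normexp. The gene Uqcrb turned from -2.58 to 0.45 at day 7 in the authors' table and its shared-probe rows, and between the days from 1.08 to -0.96 in both and to -0.0039 with normexp. Of the other list medians, 987 kept their place inside or outside the random range, 42 moved into it and 65 moved out of it. Of the other values of named genes, 647 moved by less than the spot SD and 1054 by more.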

Other observations

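Among lists not described above, cholesterol synthesis genes did not stand apart from random lists at either day (median log2 ratio 0.32 at day 7 and -0.05 at day 21), although Hmgcs1 was at -1.66 ± 0.15 and Idi1 at -1.45 ± 0.14 at day 21. Interferon response genes were at -0.57 at day 7 and -0.10 at day 21, both inside the random range (below it at day 7 in 4 of 11 alternatives), with Isg15 at -2.66 ± 0.14 and -2.27 ± 0.15. At day 7, 3 of these 14 genes were at least 2-fold higher, such as Gbp2 (1.92 ± 0.14), and 6 at least 2-fold lower. Clock genes were at -0.69 and -0.51, also inside it, with Nfil3 at -2.71 ± 0.12 and -2.90 ± 0.15. Chondro-osteogenic genes were at 0.26 and -0.37, with alkaline phosphatase (Alpl) at -2.52 ± 0.12 and -3.64 ± 0.15. At day 7, 3 of these 13 genes were at least 2-fold higher, such as Acan (at least 8.23-fold), and 3 at least 2-fold lower. Elastic fibre genes were at 0.25 and -0.54, and at day 21 the chondro-osteogenic list lay below the random range in 6 of 10 alternatives and the elastic fibre list in 5, both also on shared probes (-0.94 and -1.17). Notch and Wnt genes were at 0.71 and 0.05, mast cell genes at -0.62 and -0.05 and erythroid genes at 0.15 and -0.02. The Notch and Wnt list stayed inside the random range in 9 of 11 alternatives at day 7 and 8 of 10 at day 21, and lay above it at day 21 on shared probes (0.66). Ribosomal protein genes were at -0.98 and -0.45 and reference genes at -0.66 and 0.01, both lists inside the random range at both days, although reference genes were above it at day 21 in 3 of 10 alternatives. Thyroid and parathyroid genes were at -0.58 at day 21.

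The tests of the endothelial list in the next paragraph were chosen only after the result was seen, and those of the authors' table before.

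Endothelial genes were higher on both injured arrays, although balloon injury strips the endothelium. What is argued against is only that a lower share of smooth muscle RNA raised markers of every other cell type alike. The fibroblast median lay 2.42 below the endothelial one at day 21 (difference -2.42, 95% interval over members -3.45 to -1.18). How far a lower share raised the endothelial list stays open, because the fibroblast list was itself lower (median -0.83) and may have changed separately. A shift that varies with brightness is argued against as the larger part. Quantile and loess scaling took at most 2.92% of the list median from the members (0.0499% to 11.6%). That test did not cover an offset common to all genes, so scaling stays open at day 7. There, scaling each array on its own design left a median of 0.47, although still above the random lists drawn under that scaling. Background at low signal stays open at both days. Normexp took 23.5% (4.55% to 46.6%) at day 21 and 45.9% (23.2% to 80.3%) at day 7. Its offset of 50 is close to the raw 75th percentile of 51.6 on the uninjured array. The offset shrinks the ratios of dim genes whatever their background, so these shares cannot decide how large a part background had. At day 21 normexp left a median of 1.13, although its interval over members, from 0.07, reached the random range, up to 0.25. Endothelium missing from the uninjured sample may contribute and cannot be told apart from new vessels or regrowth: the lower quartile of the members at day 21 was 0.74, with a 95% interval of 0.00 to 1.28, and a biological difference between the arteries stays a hypothesis.

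In the authors' deposited table, 3957 of 9260 rows carry a probe that is absent from the design of the uninjured and day 21 arrays. The SD of day 7 minus uninjured was 2.79 over these rows and 1.58 over the rows with a shared probe, a ratio of 1.76 (95% interval 1.69 to 1.82), as different probes read on the designs would give. Genes of those rows differing more between arteries at any time is argued against, because the same ratio was 0.98 (0.92 to 1.03) for day 21 minus uninjured, read on 1 design. Whether they differ more at day 7 alone cannot be told from this. The intervals are over rows and hold no spread between arteries. The median difference also went opposite ways, 0.73 over these rows and -0.73 over the others at day 7. Since the columns of the table have nearly equal medians, a shift in some rows tends to be offset in the others. The opposite signs are therefore no separate evidence.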
